A study of Mus musculus with 24 samples.

How the data were processed

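RNA-seq of 10 libraries and ATAC-seq of 14 libraries of sorted mouse HSCs were used, 24 samples in all. Groups were taken from the sample labels, which give genotype, transplantation status and replicate number. Per the labels' protocols the mice were on a C57BL/6 background and of both sexes. Recipients were irradiated with 9.5 Gy and received 150 donor HSCs with competitor bone marrow, RNA libraries were made with a SMART-Seq kit, and ATAC-seq started from 10000 cells.

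The RNA values were deposited by the authors as 1 table of FPKM for 23436 gene symbols. Per the submitters' processing notes, which give no order or settings, the tools were bcl2fastq 0.3.1 and 2.17.1.14, TopHat2 2.0.14, Cuffnorm 2.2.1, Bowtie2 2.3.2, MACS2 2.1.0 and deepTools 2.4.2, with the mm10 build. Cuffnorm rescales FPKM between libraries, so a change in total RNA per cell cannot be seen. FPKM are not read counts. Values of low genes gave a depth relative to primary WT replicate 1. It was 0.8 to 1.21 in the other primary libraries from 1722 to 1813 genes. In the endogenous WT and KO libraries it was 0.83, 1.47, 1.61 and 0.89 from 440 to 804 genes. Only 4.1% to 8.3% of the endogenous ratios lay at their most frequent value, against 12.9% to 14.3% of the primary ones, so the endogenous depths are rough. Absolute depth stayed unknown. FPKM summed to 565030 to 619284 per primary library and to 728473, 1064119, 887291 and 1326786 in endogenous WT 1, WT 2, KO 1 and KO 2. Exact zeros can be failed estimates, since Ubc was at 0 in 2 libraries, so such genes are described as listed at 0 and no fold is given.

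The ATAC peaks were deposited by the authors as 1 list per library and 1 pooled list per group. The deposited fold enrichment and the deposited -log10 p and -log10 q of each peak are the authors' own, from MACS2 per the submitters' processing notes. The -log10 p and -log10 q were used to rank or filter peaks within a list. The -log10 q was also summed over lists to choose the regions named and is printed for them, though it moves with depth. Whether reads were shifted for the transposase is not given in the sources used here. The lists hold no read counts, so depth was unknown and only presence, number, length and overlap were compared, which move with depth.

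Genes with a mean of at least 1 FPKM over the 10 libraries were tested (11741) on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with an intensity trend, two-sided, and Benjamini-Hochberg adjustment over all genes at 0.05. Log2 differences are on this scale and understate the change of low genes. The first design fitted all 4 groups with 1 shared spread and gave the genotype effect in endogenous and in primary HSCs, their mean, their difference (interaction) and the transplantation effect. A fit of only the 2 groups compared was listed as its alternative, and for the primary libraries it was put first after the calls of both fits had been seen. Of 32 gene lists (programmes and markers of other cell types) 30 had at least 5 tested genes and were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for the peak lists and the plots. Peaks of the 14 lists were merged at 1 bp of overlap, and genotype or status was permuted within the other factor in exact two-sided tests. Regions were named by the gene whose span they overlap, or the nearest, from a RefSeq table of GRCm38.p6, the same assembly as mm10. That table matched 21801 of the 23436 symbols and 10991 of the tested genes.

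Design, alternatives, lists and the naming rule were fixed before the data were examined, apart from those said to have been added later. Named were the 12 genes with the largest change in each direction among those that passed and whose groups did not overlap. Where fewer than 12 passed, genes with the smallest p filled up to 6. Up to 4 members with the smallest p were named per list, with Ebf1 and the sort genes always and the 4 regions with the highest summed -log10 q per direction, of which those in or near named protein-coding genes are described. Predicted loci and microRNA or small nucleolar RNA genes were counted and not named. Alternatives were a pseudocount of 0.1, no filter or a mean of at least 5 FPKM, other scalings, library quality weights, no trend, the replicate number as a block, leaving out each library, a stricter q, equal numbers of peaks, autosomes only and a stricter overlap.

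The steps were tested on simulated data. Among 11741 simulated genes with 200 changed, the shared spread recovered 49.3%, 59.7% and 84.8% of 1.5-, 2- and 4-fold changes in endogenous HSCs with 1227 false calls, and 32.8%, 55.2% and 80.3% in primary HSCs with 1 false call. For the mean effect it recovered 58.2%, 76.1% and 89.4% with 451 false calls. Genes were drawn independently of each other, so numbers of false calls need not match those in the real libraries. The fit of the 2 primary groups recovered 91%, 98.5% and 100% with 12 false calls, and that of the 2 endogenous groups 0% at each size. For peaks, 200 one-genotype regions were planted among 20000 in exactly the pattern counted, and all were recovered. This checks the counting only and gives no sensitivity. Analyses of promoters and sequence motifs were left out because no genome sequence was used here.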

Results

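Long-term hematopoietic stem cells (HSCs) were profiled from the bone marrow of mice that carried Prx1-Cre, a recombinase active in limb mesenchymal stroma. The donors were either Ebf1 wild-type (WT) or homozygous for a floxed Ebf1 allele (KO), so that the transcription factor EBF1 was deleted in stromal cells and not in the HSCs. The series title states the question: whether mutant stroma leaves lasting changes in HSCs. Cells were sorted as lineage-negative, Sca-1-positive, Kit-positive, CD150-positive. They came either directly from the mutant or control animals (endogenous), or after 150 donor HSCs had been transferred into irradiated wild-type recipients (primary), or after a second transfer (secondary). RNA-seq covered 10 libraries, with 2 WT and 2 KO endogenous and 3 WT and 3 KO primary libraries. ATAC-seq, which marks open chromatin by transposition, covered 14 libraries, with 2 WT and 2 KO endogenous, 2 WT and 2 KO primary, and 3 WT and 3 KO secondary libraries. No label says that replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical.

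The RNA values were FPKM (fragments per kilobase of transcript, scaled to the size of the library), and the read depth behind them was unknown in absolute terms. Genes above 0 FPKM numbered 13048 to 14192 in the endogenous libraries and 15587 to 15824 in the primary libraries. The 10 most abundant genes held 7.7% to 9.8% of the summed FPKM in primary libraries, against 8.7% and 15.2% in endogenous WT and 25.7% and 32.2% in endogenous KO libraries. Replicates were much closer to each other after transplantation. Among 2374 genes with a mean above 50 FPKM, the median SD of log2(FPKM + 1) was 0.0345 in primary WT and 0.0457 in primary KO, against 0.282 in endogenous WT and 0.278 in endogenous KO. The pairwise correlation of replicates was 0.979 to 0.993 in the primary groups and 0.905 and 0.924 in the endogenous groups.

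Ebf1 itself was at 0 to 0.285 FPKM in all 10 libraries. It was listed at 0 in 3 of the 4 endogenous libraries, which can be a failed estimate, and was deleted in stroma and not in HSCs, so its level does not check the genotype labels. Ly6a, Kit and Slamf1, which encode the markers the cells were sorted for, were above 0 in every library. Cd48, another stained marker, found on more committed progenitors, was at 1.44 and 6.84 FPKM in endogenous WT and 9.72 in endogenous KO replicate 1. It was listed at 0 in endogenous KO replicate 2 and lay at 0.761 to 1.19 FPKM in the primary libraries. The lineage genes Cd3e and Cd19, also stained, were listed at 0 in 4 and in 3 of the 4 endogenous libraries. In the primary groups Kit was 303 ± 9.85 FPKM in WT and 319 ± 6.84 in KO (SD, n = 3 each), and Ly6a, which encodes Sca-1, was 118 ± 4.62 and 117 ± 6.97. Flt3 stayed low, at 2.68 ± 0.139 and 2.79 ± 0.0640 FPKM. Slamf1, which encodes the sort marker CD150, was 41.5 ± 1.09 FPKM in WT and 48.9 ± 1.78 in KO, and Cd34 was 56.5 ± 1.83 and 50.9 ± 1.11. In the fit of the 6 primary libraries both differences passed, with a limma Benjamini-Hochberg adjusted p of 0.0121 for Slamf1 and 0.0359 for Cd34. In endogenous WT and KO libraries mean Kit was 98.0 and 110.5 FPKM and mean Slamf1 20.1 and 16.5, below the primary means. Mean Flt3 was 4.28 and 7.27 FPKM there and mean Cd34 86.1 and 90.1, above the primary means. These sort genes thus differed between endogenous and primary libraries as well.

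Primary transplanted HSCs were compared first, to ask whether cells from mutant stroma still differed after transfer to normal recipients. Transferred KO-donor HSCs carried less RNA of the cell cycle and of the megakaryocyte and platelet programme than transferred WT-donor HSCs, and more immediate early RNA, in all 3 libraries against all 3. With an estimated correlation the adjusted p was 0.0359 for the cell cycle, 0.0775 for the megakaryocyte programme and 0.0571 for immediate early genes in the fit of the 6 primary libraries, and 0.0647, 0.0629 and 0.0647 in the design fixed first. Most of the differences were small. Pf4, the platelet chemokine, fell from 909 ± 31.3 to 471 ± 33.4 FPKM (SD, n = 3 each), 0.518 times the WT level. Ccnb2, a mitotic cyclin, fell from 114 ± 0.532 to 88.6 ± 1.15 FPKM, and Egr1, an immediate early transcription factor, rose from 169 ± 8.86 to 282 ± 11.8 FPKM.

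The design fixed first shares 1 estimate of the spread with the more variable endogenous libraries. In that design limma called 0 genes, with 146 (1.2%) at an unadjusted p under 0.05, below the share of 0.05 that chance gives. The smallest adjusted p there was 0.266, for Isl1 and Thg1l, then 0.289 for Wdfy1, with Nkg7, Tfpi, Rhob, Plek, Gp1bb, Bdh2 and Matn4 also among the smallest p and not passing. All calls given here come instead from limma fitted to the 6 primary libraries alone, in which 963 of 11741 genes passed (347 higher and 616 lower in KO). That fit was listed before the data were examined, but it was put first only after the spreads of the 2 settings and the calls of both fits, 0 and 963, had been seen, and its tests of gene lists were added then. Its adjusted p therefore take no account of the choice between the fits. The design fixed first called 16 lists by camera, with adjusted p of 2.76e-24 for the cell cycle, 4.39e-21 for immediate early genes and 6.29e-12 for megakaryocyte genes, where 3 lists held with an estimated correlation, each at an adjusted p of 0.0408 (ageing and platelet bias, neutrophil markers, interferon response). Of the 963 calls 49 reached 1.5-fold, and 33 of those were higher in KO. The groups did not overlap in any of the 963 genes. Across all tested genes 3587 did not overlap (30.6%, where chance gives 10% for 3 against 3). Quantile normalization gave 820 calls split as 400 higher and 420 lower, so the share of higher calls depends on the scaling. Leaving out a library left 2 against 3 and gave 287 calls without WT replicate 1, 399 without WT replicate 2, 356 without WT replicate 3, 551 without KO replicate 1, 1104 without KO replicate 2 and 371 without KO replicate 3, and 241 genes were called in every one of these fits. Of the 16 lists camera called in this fit, only the cell cycle held with an estimated correlation. At the preset correlation 13 of the 16 kept their call and direction under all 11 other scalings, pseudocounts, filters and left-out libraries run. The sex-linked genes kept theirs under 10, since too few of them had a mean of at least 5 FPKM to be tested there, and 2, the Myc targets and the inflammation genes, lost it under some.

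Of 44 measured genes of S phase and G2/M, 34 fell and 0 rose over all genes tested, and 39 fell and 1 rose when adjusted over the list alone. The median log2 difference was -0.24 (camera adjusted p = 4.75e-24; adjusted p = 0.0359 with an estimated correlation, the only list to hold there). Ccnb2 fell by 0.36 ± 0.022 on the log2 scale (SE) and Aurkb, a mitotic kinase, fell by 0.38 ± 0.0273, with limma adjusted p of 0.000617 and 0.000803. Ccna2 and Ccnb1, the cyclins of S phase and mitosis, fell to 0.779 and 0.738 times their WT FPKM. Without WT replicate 1 the 34 became 20. DNA repair genes followed, with 6 of 31 lower and 0 higher (also 6 adjusted over the list alone; camera adjusted p = 9.06e-05; adjusted p = 0.0775 with an estimated correlation). Among them were H2afx at -0.33 and Blm at -0.27 log2, then Rad54l and Lig1, and the 6 became 2 without WT replicate 1 and 3 without WT replicate 2, WT replicate 3 or KO replicate 3.

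Oxidative phosphorylation transcripts moved the same way but by less. All 70 members had a lower mean in KO, with a median log2 difference of -0.14. Of these, 15 passed over all genes and 34 when adjusted over the list alone, with 0 higher in either count (camera adjusted p = 4.51e-15; adjusted p = 0.295 with an estimated correlation). Cycs, which encodes cytochrome c, fell from 60.8 ± 0.343 to 49.6 ± 0.720 FPKM (n = 3 each), and Sdhb, Ndufv2 and Uqcrq, subunits of complexes II, I and III, fell by 0.18, 0.14 and 0.23 on the log2 scale. The count rested on single libraries, with 39 members lower without KO replicate 2 and 1 to 4 without any other, and was 8 with quantile normalization. Among 33 targets of Myc and genes of ribosome biogenesis, 4 fell and 1, Mycn, rose (11 and 3 adjusted over the list alone; camera adjusted p = 0.0251; adjusted p = 0.244 with an estimated correlation). That call was lost with quantile normalization (camera adjusted p = 0.368, 2 higher and 1 lower), at a mean of at least 5 FPKM (0.0703), with the trend of gene span removed (0.0558), without WT replicate 1 (0.0631) and without KO replicate 2 (0.145). Its 4 lower members became 0 without WT replicate 1, WT replicate 3 or KO replicate 3, 1 without WT replicate 2 and 2 without KO replicate 1.

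The megakaryocyte and platelet programme fell in 16 of 29 members and rose in 3 (17 and 4 adjusted over the list alone), with a median of -0.17 log2 (camera adjusted p = 6.67e-06; adjusted p = 0.0775 with an estimated correlation). Pf4 fell by 0.95 ± 0.0569 on the log2 scale (SE; limma adjusted p = 0.000617). Plek, a platelet kinase substrate, fell from 68.7 ± 1.42 to 44.1 ± 0.499 FPKM, and Gp5, part of the von Willebrand factor receptor, fell from 67.6 ± 1.31 to 45.6 ± 1.60. Itga2b, which encodes CD41, fell to 0.787 times the WT level. The 3 members that rose, named after their values were seen, were Clu, Fhl1 and Selp, each by 0.15 to 0.16 log2, and all 3 also belong to the list of HSC ageing and platelet bias. The members that rose became 0 without WT replicate 3 and 1 without WT replicate 1, WT replicate 2 or KO replicate 3.

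That list, transcripts reported to rise with age in HSCs, went the other way, with 13 of 28 members higher and 0 lower (16 and 0 adjusted over the list alone) and a median of 0.15 log2 (camera adjusted p = 4.90e-10; adjusted p = 0.0571 with an estimated correlation). Neo1, which encodes the receptor neogenin, rose from 12.6 ± 0.0489 to 20.9 ± 0.823 FPKM, and Plscr2 and Cd38 rose by 0.36 and 0.30 log2. HSC identity genes rose in 6 of 30 members and fell in 0 (12 and 0 adjusted over the list alone; median 0.07 log2; camera adjusted p = 1.31e-06; adjusted p = 0.0571 with an estimated correlation). Mycn rose by 0.21, Sult1a1 by 0.32 and Slamf1 by 0.23 log2, and Prdm16, a regulator of HSC maintenance, by 0.25. The 13 ageing genes became 8 without WT replicate 2, WT replicate 3 or KO replicate 3, and the 6 identity genes became 2 without KO replicate 3 and 3 without KO replicate 1 or any 1 WT library.

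Immediate early and AP-1 transcripts rose in 18 of 29 members and fell in 0 (20 and 1 adjusted over the list alone), with a median of 0.28 log2 (camera adjusted p = 4.38e-16; adjusted p = 0.0571 with an estimated correlation). Egr1 rose by 0.74 ± 0.0469 (SE; limma adjusted p = 0.00064), Zfp36 from 392 ± 10.4 to 589 ± 21.3 FPKM, Fos from 559 ± 21.0 to 856 ± 36.0 and Dusp1, a MAP kinase phosphatase, from 385 ± 9.22 to 536 ± 18.4. Of 29 quiescence regulators 5 rose and 1 fell (7 and 2 adjusted over the list alone; camera adjusted p = 0.00938; adjusted p = 0.167 with an estimated correlation). They included Egr1 and Nr4a1, which are also immediate early genes, with Pbx1 at -0.22 log2 and Txnip at 0.25. Interferon response genes rose in 7 of 43 and fell in 0 (13 and 0 adjusted over the list alone; camera adjusted p = 1.19e-05; adjusted p = 0.0775 with an estimated correlation), with Gbp6 rising from 9.02 to 14.5 FPKM and Oas2 from 3.23 to 4.64. The 18 immediate early genes became 11 without KO replicate 3, and the 5 quiescence regulators that rose became 2 without WT replicate 1 or KO replicate 3 and 3 without WT replicate 2 or 3. The 7 interferon genes became 2 without WT replicate 1 or KO replicate 3, 3 without WT replicate 3, 4 without WT replicate 2 or KO replicate 1, 11 with quantile normalization and 12 with the trend of gene span removed.

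Markers of mature cells, which the sort should remove, also moved with the genotype. Not all were at low levels, since Padi4 of the neutrophil list was 64.3 ± 0.380 FPKM in WT and 74.3 ± 0.302 in KO (SD, n = 3 each). Of 15 erythroblast markers 6 rose and 0 fell, including Rhd from 1.51 to 3.32 FPKM and Car1 from 14.8 to 21.6 (6 and 0 adjusted over the list alone; camera adjusted p = 9.64e-05; adjusted p = 0.119 with an estimated correlation). Of 11 neutrophil markers 4 rose, with Camp at 4.64 and 8.28 FPKM (4 and 0 adjusted over the list alone; camera adjusted p = 0.000347; adjusted p = 0.135 with an estimated correlation). The sex-linked genes differed too. Xist, transcribed from the inactive X chromosome, was 19.5 ± 1.11 FPKM in WT and 13.9 ± 0.833 in KO, and Eif2s3y, Uty, Ddx3y and Kdm5d of the Y chromosome were 0.46, 0.51, 0.28 and 0.33 log2 higher in KO (4 of 5 sex-linked genes higher and 1 lower, the same adjusted over the list alone; camera adjusted p = 0.0065; adjusted p = 0.204 with an estimated correlation). All 6 primary libraries held both Xist and Y-linked RNA, at levels that lay close together within a group. Ddx3y was 9.61, 10.2 and 10.5 FPKM in WT and 12.4, 12.3 and 12.6 in KO. Libraries split from 1 pool of both sexes per genotype would look like this, which was not tested. The 3 libraries of a group are thus not established as biological replicates, and their SDs and p-values may reflect technical spread alone. The 6 erythroblast markers became 3 without WT replicate 3, the 4 neutrophil markers 1 without KO replicate 3 and 2 without any 1 WT library, the 4 sex-linked genes 2 without WT replicate 1 or KO replicate 3, and the erythroblast and neutrophil markers 2 each at a mean of at least 5 FPKM.

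Among single genes the named 12 with the largest rise were led by Isl1, a LIM-homeodomain factor, at 0.500 ± 0.0949 FPKM in WT and 3.81 ± 0.387 in KO. Xlr3a, one of a family of close copies and so uncertain, went from 0.287 to 2.81 and Thg1l, a transfer RNA guanylyltransferase, from 9.21 ± 0.636 to 23.6 ± 0.910 FPKM. Myl10, a myosin light chain, went from 93.7 ± 3.16 to 187 ± 9.69 FPKM, and Cyr61, a matricellular protein, from 2.39 ± 0.222 to 6.16 ± 0.720 FPKM. Clec2d, Ly6k, Rpl39l, Igj, Gbp11, Creb5 and Slc15a2 rose by 0.87 to 1.26 log2. Clec2d was uneven among the KO libraries (22.5, 14.5 and 10.9 FPKM). On the other side Prg2, the eosinophil major basic protein, fell from 3.10 ± 0.295 to 0.596 ± 0.139 FPKM and Wdfy1 from 38.7 ± 2.74 to 16.0 ± 1.90 FPKM. F2rl2, a thrombin receptor of platelets, fell by 0.95 and Nkg7, a cytotoxic granule protein, from 65.9 ± 1.50 to 39.9 ± 0.163 FPKM. The rest of the 12, Pitx2, Rgs10, Eps8l1, Fcer1a, Serpine2, Ache and Cd180, fell by 0.66 to 0.93 log2.

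**Figure D1:**
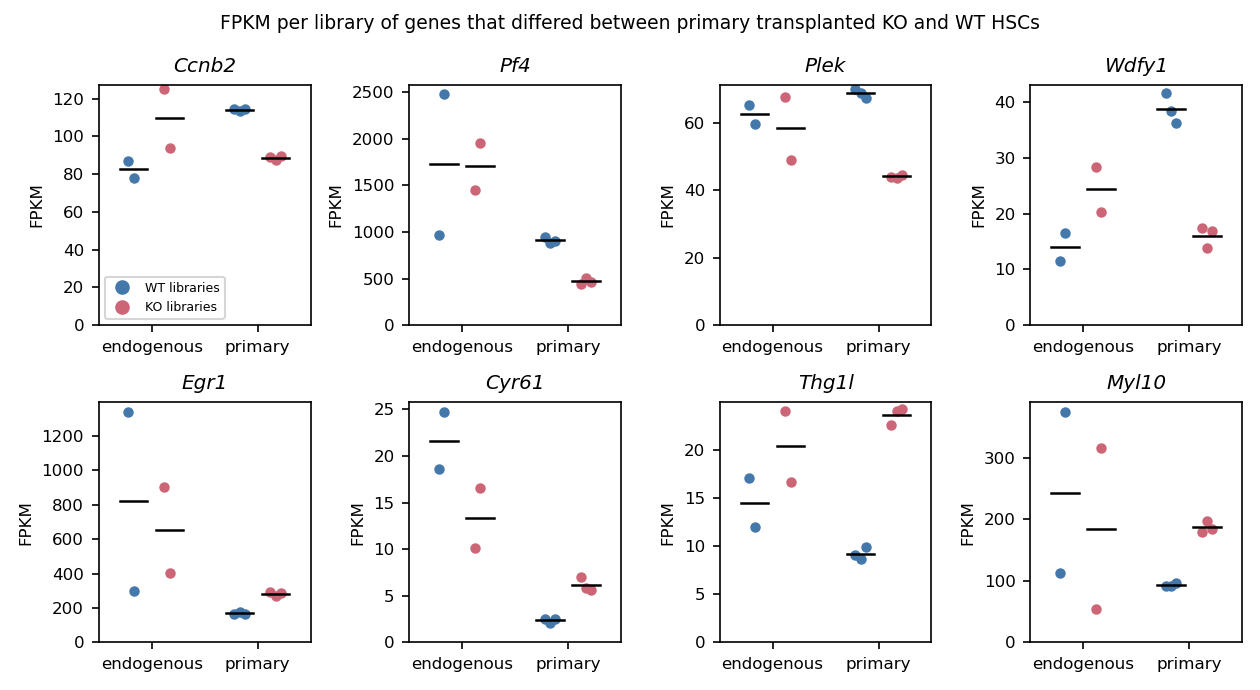
FPKM per library (points) and group mean (black lines) of 8 genes in endogenous and primary transplanted HSCs from WT (blue) and KO (red) donors, each panel with its own linear axis from 0. In the primary groups the 3 KO points of Ccnb2, Pf4, Plek and Wdfy1 lie below, and those of Egr1, Cyr61, Thg1l and Myl10 above, all 3 WT points, while the 2 endogenous points of a group lie far apart for several genes, as for Egr1 and Myl10.

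Endogenous HSCs were compared next, to ask how resident HSCs of mutant stroma differ from those of control stroma. KO cells had higher erythroid and lower TGF-beta, BMP, Notch and Wnt pathway RNA as groups, but few single genes stood clear of the spread between 2 libraries. These groups passed by camera, with an adjusted p of 0.179 for erythroblast markers, 0.179 for the erythroid programme and 0.186 for the pathway genes with an estimated correlation, and without WT replicate 1 all 3 lost the camera call (adjusted p = 0.228, 0.691 and 0.441). Globin levels differed widely between single libraries. Hbb-bs was 3.47 and 56.8 FPKM in WT against 32.3 and 612 in KO, and Hba-a1 was 7.07 and 62.4 against 31.1 and 535.5. Hba-a1 shares reads with the near-identical Hba-a2, so its level is uncertain. Hes1, a Notch target, was 105 and 57.3 FPKM in WT and 18.8 and 33.1 in KO, a log2 difference of -1.60 ± 0.314 (SE) that missed the threshold (limma adjusted p = 0.0511).

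In the design with the shared spread limma called 173 genes (108 higher and 65 lower in KO). Of these, 15 were listed at 0 in a whole group. The named genes that were higher included S100a9, a calcium-binding protein of neutrophils, at 0 and 2.68 FPKM in WT against 11.4 and 18.9 in KO, and Cpa3, the mast cell carboxypeptidase, at 0 and 2.14 against 11.9 and 7.94. Qpct, Gfod2, Zswim3, Gramd3, Bbs12, Nupr1l and Zfp133-ps rose by 2.05 to 2.24 log2 and the small nuclear RNA Rnu12 by 4.06. Rnase12 was listed at 0 in both WT libraries and at 3.29 and 5.48 FPKM in KO. H2-Q6, one of a family of close copies and so uncertain, was 0.00303 and 0.00477 FPKM in WT and 34.5 and 5.76 in KO, and was listed at 0 in the 3 primary WT libraries. Those that were lower included C1ra and Serping1, a protease and an inhibitor of the classical complement pathway, at 9.78 and 8.76 against 3.09 and 1.81 FPKM, and at 2.92 and 2.14 against 0.0473 and 0.0841. Il1r2, the interleukin-1 decoy receptor, fell by 1.75 and Tlr6 by 2.11 log2. Tm4sf1, Rnd3, Rapgef3, Plekhb1, Wdr19, Dleu7 and Plekhg6 fell by 1.61 to 1.90 log2. Ubc, a polyubiquitin gene that every cell uses, was listed at 0 in both KO libraries and at 423 and 322 FPKM in WT. With only the 4 endogenous libraries in the fit, limma called 2 genes, Ubc and a small nucleolar RNA. An unadjusted p under 0.05 was reached by 175 genes (1.5%), below the share of 0.05 that chance gives. In simulated libraries with the observed spread this design made 1227 false calls here, and without 1 endogenous library the count went to 3824 (WT replicate 1), 2040 (WT replicate 2), 2043 (KO replicate 1) and 843 (KO replicate 2). Without any 1 primary library it was 3 or 4, so the 173 genes are not established as genotype differences. The simulation drew genes independently and gave more false calls than the 173 calls made in all. Its 1227 therefore does not estimate how many of the 173 are false.

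By list, 14 of 15 erythroblast markers had a higher mean in endogenous KO cells, with a median of 0.64 log2 (camera adjusted p = 0.0104; adjusted p = 0.179 with an estimated correlation), and 19 of 24 genes of the erythroid programme did, with a median of 0.47 (camera adjusted p = 0.0162; adjusted p = 0.179 with an estimated correlation). No single member passed over all genes, and adjusted over the list alone 0 and 2 passed. With 1 endogenous library left out, which raised the count of calls as given above, 1 to 7 and 3 to 7 members were called higher. Gfi1b, a transcriptional repressor required for erythroid and megakaryocyte development, was 84.3 and 72.7 FPKM in WT and 139 and 107 in KO. Of 30 genes of TGF-beta, BMP, Notch and Wnt signalling 8 had a higher mean in KO and the median was -0.32 log2 (0 called over all genes, 2 lower adjusted over the list alone; camera adjusted p = 0.00641; adjusted p = 0.186 with an estimated correlation). Id2 was 41.7 and 27.7 against 19.8 and 20.3 FPKM. Heat shock and unfolded protein genes had a median of -0.14 log2 (0 called in either count; camera adjusted p = 0.0162; adjusted p = 0.179 with an estimated correlation), with Hyou1 at 10.4 and 7.89 against 5.52 and 2.71 FPKM. Without WT replicate 1 all 4 lists lost their call, with adjusted p of 0.228, 0.691, 0.441 and 0.691 in the order given. Without KO replicate 1 they were at 0.111, 0.256, 0.0871 and 0.369, and without WT replicate 2 the erythroblast markers were at 0.185. The median of the erythroblast markers was then 0.99 log2 without WT replicate 1 (14 of 15 higher), 0.30 without KO replicate 1 (9 of 15) and 0.28 without WT replicate 2 (11 of 15), against 0.64 with all 4 libraries.

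**Figure D2:**
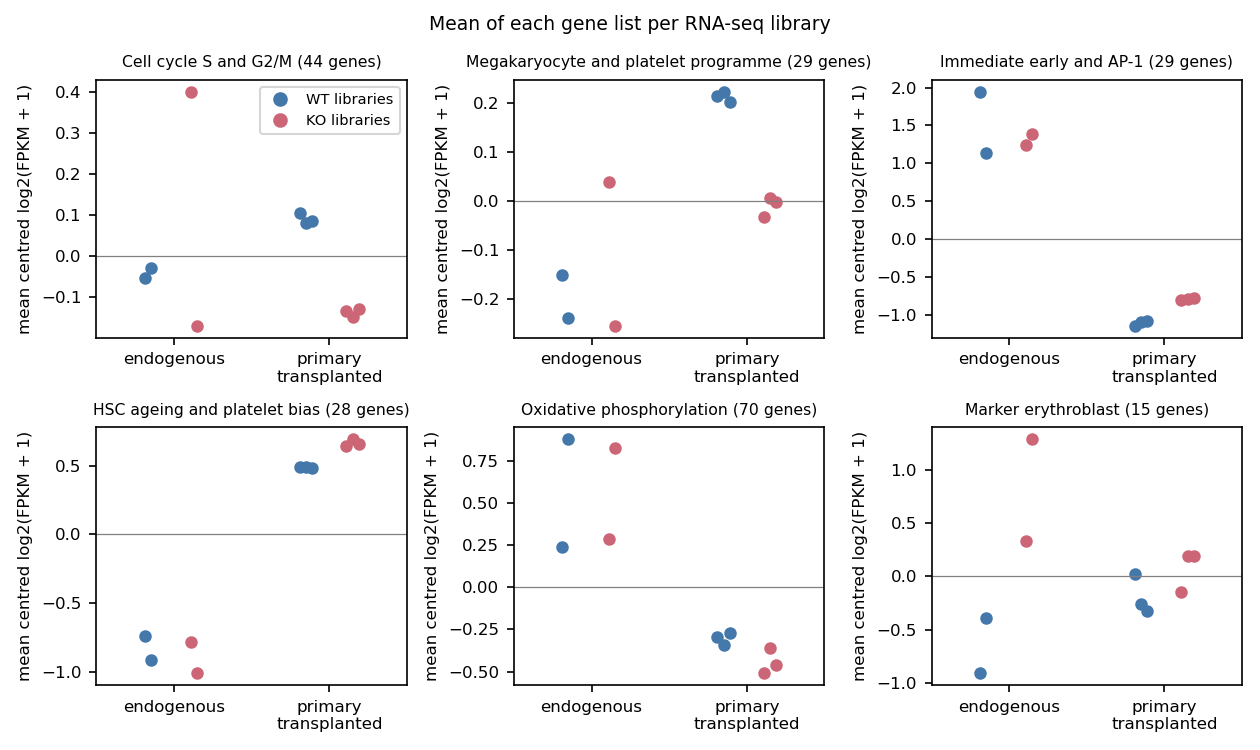
Mean over the genes of 6 lists of log2(FPKM + 1), centred per gene on its mean over the 10 libraries, with 1 point per library (WT blue, KO red) in endogenous and primary transplanted HSCs. The 3 primary libraries of a genotype lie close together and apart from the other genotype for the cell cycle, megakaryocyte, immediate early and ageing lists, while the 2 endogenous libraries of a genotype lie further apart in some lists, as for immediate early genes in WT (1.946 and 1.134), and close in others, as for the cell cycle in WT (-0.054 and -0.03).

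A correlation across genes between the genotype differences of the 2 settings was not established. The endogenous differences came from 2 libraries per genotype with a wide spread, so shared differences as small as most primary ones could have gone unseen. The log2 differences in endogenous and in primary HSCs, which share no library, had a Pearson r of -0.073 and a Spearman rho of -0.029 across 11741 genes, which are not independent replicates. Relabelling genotype within setting in all 120 ways gave p = 0.167 for r and 0.7 for rho (exact permutation, two-sided). Gene by gene, Myl10 was 112 and 375.5 FPKM in endogenous WT and 54.9 and 316 in endogenous KO, and Wdfy1 was 11.5 and 16.6 against 28.4 and 20.3. Pf4 was 972 and 2480 against 1447 and 1959. Of the 173 endogenous calls, 10 were also called in the primary libraries, a smaller share than the 8.2% of all tested genes called there. For the mean of both genotype effects limma called 3 genes (1 higher, 2 lower), Ubc with 2 small RNAs, all with a group listed at 0. An unadjusted p under 0.05 was reached by 1241 genes (10.6%, where chance gives a share of 0.05). By list, erythroblast markers were higher on average (median 0.58 log2; 0 members called in either count; camera adjusted p = 0.000506; adjusted p = 0.111 with an estimated correlation), as were mast cell and basophil markers (7 of 7 positive; 0 called, 1 adjusted over the list alone; camera adjusted p = 0.0135; adjusted p = 0.294 with an estimated correlation). The erythroid programme, the TGF-beta, BMP, Notch and Wnt genes and the heat shock genes had medians of 0.21, -0.15 and -0.08 log2, with 0 members called in either count, each at a camera adjusted p of 0.00869 (adjusted p = 0.131, 0.294 and 0.131 with an estimated correlation). Without endogenous WT replicate 1 all 5 lists lost their camera call, with adjusted p of 0.0504, 0.108, 0.645, 0.473 and 0.507 in the order given, and without endogenous KO replicate 1 all but the erythroblast markers did (0.44, 0.168, 0.128 and 0.218). Mast cell and basophil markers also lost it without endogenous WT replicate 2 (0.15), with a pseudocount of 0.1 (0.0948) and without a filter (0.305), and heat shock genes with quantile normalization (0.0637).

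Transplanted and endogenous HSCs of both genotypes were then compared as background to the genotype effect. Transplanted cells had far less immediate early RNA, less RNA for oxidative phosphorylation and more RNA of the ageing and platelet-bias list. These lists passed by camera, while the adjusted p was 0.385, 0.518 and 0.0696 with an estimated correlation. Jund was 580 and 377 FPKM in endogenous WT libraries and 2.79 ± 0.293 (SD, n = 3) in primary WT libraries, and Klf2 was 461 and 264 against 6.40 ± 0.980. Vwf, the von Willebrand factor of platelet-biased HSCs, was 3.87 times higher in primary libraries. The setting is confounded with any difference in library preparation or sequencing between the endogenous and the transplanted libraries, for which the labels give no batch, so these values cannot be assigned to transplantation.

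Limma called 7066 of 11741 genes (3515 higher and 3551 lower in transplanted cells), and 567 reached 4-fold, of which 456 were lower. Of 29 immediate early genes 26 fell and 1 rose (26 and 1 adjusted over the list alone), with a median of -1.85 log2 (camera adjusted p = 4.41e-10; adjusted p = 0.385 with an estimated correlation), led by Atf3 at -5.87 and Ier5 at -4.51. Of 70 oxidative phosphorylation genes 59 fell and 1 rose (60 and 1 adjusted over the list alone; 40 and 8 with quantile normalization; median -1.05; camera adjusted p = 1.90e-10; adjusted p = 0.518 with an estimated correlation), including Cycs, Uqcrb and Ndufb3 at -1.30, -1.57 and -1.70. Ageing and platelet-bias genes rose in 24 of 28 and fell in 1 (25 and 1 adjusted over the list alone; median 1.65; camera adjusted p = 1.08e-08; adjusted p = 0.0696 with an estimated correlation), with Alcam at 4.01 times and Cd38 at 2.97 times the endogenous FPKM. Quiescence regulators split, with 17 lower and 7 higher both over all genes and adjusted over the list alone (camera adjusted p = 0.0478; adjusted p = 0.385 with an estimated correlation). Tgfb1 fell by 3.57 and Foxo3 rose by 2.68 log2. Of 77 cytoplasmic ribosomal protein genes 32 were called lower and 2 higher (11 and 1 adjusted over the list alone; camera adjusted p = 0.00943; adjusted p = 0.812 with an estimated correlation), a direction that turned with quantile normalization (10 lower and 29 higher; camera adjusted p = 0.245). With the trend of gene span removed their median went from -0.658 to -0.212 and the call was lost (0.565), as it was without endogenous WT replicate 2 (0.257) or KO replicate 2 (0.256), with 11 lower in each, while 54 were lower without endogenous WT replicate 1 or KO replicate 1 and 17 to 23 without any 1 primary library. Neutrophil markers rose in 8 of 11 and fell in 1 (9 and 1 adjusted over the list alone; camera adjusted p = 0.022; adjusted p = 0.339 with an estimated correlation). Their call was lost at a mean of at least 5 FPKM (0.108) and without endogenous WT replicate 1 (0.0761) or KO replicate 1 (0.0666), and that of the quiescence regulators at a mean of at least 5 FPKM (0.0775) and without any 1 endogenous library (0.0561 to 0.0934). The median of all genes was 0.029 log2 as deposited and 0.107 after quantile normalization.

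Of the named genes that rose with transplantation, Mdfi went from 3.01, 4.75, 2.68 and 0.694 FPKM to 60.3 ± 1.38 in WT and 57.6 ± 2.58 in KO (SD, n = 3 each). Erg, an ETS factor needed by HSCs, rose by 3.52 and Bak1, an effector of apoptosis, by 3.85 log2. Neo1, Klrb1c, Vat1, Eif3j1, Ssh3, Prrg4, Zc3h7b and Atf7ip rose by 2.99 to 4.07 log2, of which Eif3j1 was uneven among primary libraries (14.2 to 47.8 FPKM). Besides Jund and Atf3, those that fell were Cebpb at -6.51, Taf10 at -6.40, Klf2 at -5.53, Alyref at -5.34, Nr4a1 at -5.23, Siah2 at -5.17, Id3 at -4.71, Frat2 at -4.69 and Dusp5 at -4.65. Rps27 and Rps27rt, near-identical copies whose reads the counting could split, went opposite ways: Rps27rt was at 3560, 7945, 3624 and 8049 FPKM in endogenous libraries and listed at 0 in all 6 primary libraries, whereas Rps27 rose by 2.98 log2, so neither value is certain.

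Chromatin accessibility was compared from the deposited peak lists, to ask whether genotype differences were present before and after transfer. In endogenous and secondary libraries another split of the same libraries gave more regions called in 1 group alone than the genotypes did, and in primary libraries the genotypes gave the most, in a design where the smallest possible share of relabellings is 0.333. Peaks per library numbered 30888 and 48867 in endogenous WT and 16947 and 29543 in endogenous KO. In primary cells they were 28899 and 20068 in WT and 28219 and 29657 in KO, and in secondary cells 28224, 13912 and 26876 in WT and 25990, 25453 and 30892 in KO. The mean was 28248 ± 10854 in WT and 26672 ± 4724 in KO (SD, n = 7 each). The KO minus WT difference averaged over the 3 settings was -2579 peaks (exact permutation within setting, two-sided p = 0.664, smallest possible 0.0028) and -0.61 Mb of covered genome (exact permutation p = 0.756). At a -log10 q of at least 5 the difference in peaks was far smaller and that in length reversed. Within endogenous, primary and secondary libraries the exact permutation p was 0.333, 0.667 and 0.6 for the number of peaks, where the smallest possible values are 0.333, 0.333 and 0.1. By setting, primary libraries differed from endogenous ones by -4850 peaks (exact permutation p = 0.611, smallest possible 0.0556), and secondary libraries differed from endogenous ones by -6337 and from primary ones by -1486 (exact permutation p = 0.35 and 0.68, smallest possible 0.01). Both differences from endogenous libraries reversed at a -log10 q of at least 5.

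**Figure D3:**
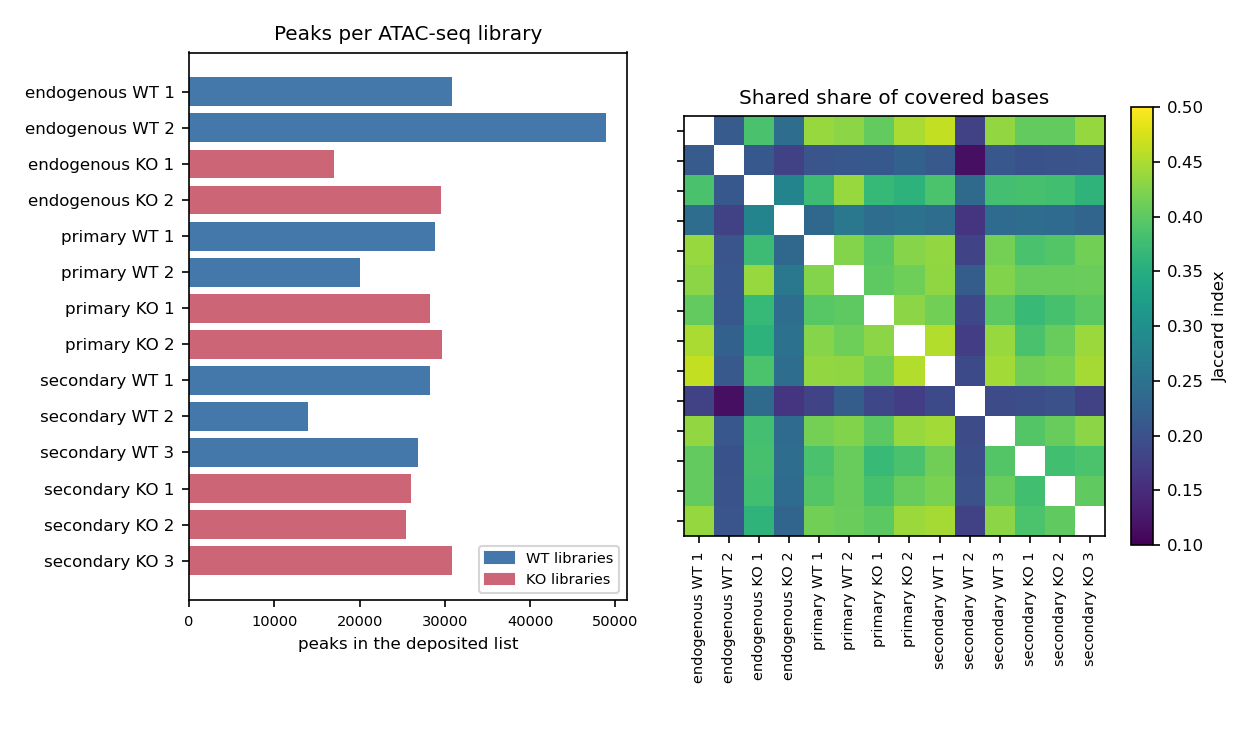
Left, number of peaks in the deposited list of each of 14 ATAC-seq libraries (WT blue, KO red). Right, Jaccard index of covered bases for each pair of libraries, rows in the same order as columns and the diagonal left blank; endogenous WT replicate 2, endogenous KO replicate 2 and secondary WT replicate 2 share least with the rest, with mean indices of 0.2, 0.234 and 0.185.

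The 14 lists merged into 117238 regions, of which 73795 (62.9%) were called in 1 list and 4977 (4.2%) in all 14. No region was called in all 7 libraries of one genotype and in none of the other, and the highest count among the other relabellings drawn (100 in all) was 6. Within the endogenous libraries 2387 regions were called in both WT and no KO library and 199 the other way, and with the same number of strongest peaks taken from each list 467 and 418. The split of WT 1 and KO 1 against WT 2 and KO 2 gave 4206 such regions, more than the 2586 of the genotypes. In the primary libraries the counts were 863 and 2200 (3063 together, highest other split 2333), and 750 and 848 with the same number of strongest peaks. In the secondary libraries they were 48 and 267 (315 together, highest other split 837), and 47 and 152 with the same number. The imbalance between the genotypes in endogenous and primary libraries thus moved with the lengths of the lists. Such counts were reached by a share of 0.667, 0.333 and 0.9 of the relabellings, of which the smallest possible shares are 0.333, 0.333 and 0.1. Libraries of 1 genotype were no more alike than libraries of different genotypes, with a mean Jaccard index of 0.334 within and 0.337 between (exact permutation p = 0.789, smallest possible 0.0111).

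Regions that separated the genotypes in endogenous cells were followed after transfer. Of the 2586, 97 (3.75%) differed the same way in primary libraries and 122 (4.72%) the opposite way (exact permutation p = 1, smallest possible 0.333), and in secondary libraries 7 and 28 (exact permutation p = 0.9, smallest possible 0.1). The same-way minus opposite-way difference reversed with the same number of strongest peaks from each list, from -0.97 to 1.47 points in primary and from -0.81 to 0.11 in secondary libraries. It also reversed without endogenous KO replicate 1 (0.38), primary WT replicate 2 (0.73) or primary KO replicate 2 (1.62), and in secondary libraries without secondary WT replicate 2 (0.73). In either direction these were 8.47% and 1.35% of the 2586, where 2.61% and 0.27% of all 117238 regions, most of them called in 1 list, separated the genotypes in primary and in secondary libraries. The strongest WT region of the endogenous comparison lay inside Abcb4 (mm10, chromosome 5, 8916847 to 8917586). It had a -log10 q of 38 and 21.9 in the WT lists and was called in 6 of the 14 lists, 4 WT and 2 KO, so that its pattern did not carry over. A second region of Abcb4 (chromosome 5, 8943862 to 8945344) was called in 12 lists, and a region inside Arpp19 (chromosome 9, 75037374 to 75038304) was called in 9 lists, 5 WT and 4 KO. The strongest KO region lay inside Sfi1 (chromosome 11, 3179742 to 3180337) and was called in 6 KO and 2 WT lists. It separated the primary libraries the same way, with a -log10 q of 40.3 and 45.7 in the KO lists and no call in WT, and was called in 2 WT and 2 KO secondary lists. A region inside Dhx8 (chromosome 11, 101739923 to 101740770) was called in 4 KO lists and 1 WT list.

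In primary cells the WT-only regions with the highest scores included one inside Dlgap1 (chromosome 17, 70501758 to 70502439), called in 10 lists, and one inside Tle4 (chromosome 19, 14485062 to 14485792), called in 8 lists, 6 WT and 2 KO. The KO-only region with the highest score (chromosome 13, 120321390 to 120321640, 3129 bp from Tcstv3) had a -log10 q of 1677 and 1651, against 1735 in endogenous KO replicate 2 and 1121 in secondary WT replicate 1 and no call in the 10 other lists. In secondary cells a region inside Rilpl2 (chromosome 5, 124475105 to 124475507) was called in the 3 secondary WT lists and nowhere else, and one inside Snx30 (chromosome 4, 59825515 to 59826152) in 6 WT lists and 1 KO list. The KO-only regions inside Zfp141 (chromosome 7, 42495886 to 42496895) and Polr3e (chromosome 7, 120918367 to 120918822) were called in 11 and 8 lists. Those inside Macir (chromosome 1, 97649849 to 97650791) and 3181 bp from Pip5k1a (chromosome 3, 95054551 to 95055349) were called in 9 and 7 lists. Whether these positions are exonic or intronic was not determined, since gene spans were the only annotation used here. No filter for repeated sequence was applied here either. Reads from repeats were thus not excluded as a source of the named regions, including those inside Sfi1 and near Tcstv3.

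The pooled lists, 1 per genotype and setting and so without replicates, shared 54.5% of WT and 58.6% of KO peaks in endogenous cells, 82.6% and 58.2% in primary cells and 76.3% and 66.2% in secondary cells. They held 18887 WT-only and 16281 KO-only peaks in endogenous cells, 5622 and 18867 in primary cells, and 10719 and 17590 in secondary cells. The longer primary and secondary pooled lists were those of KO, with 45155 against 32311 and 52054 against 45261 peaks.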

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

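The genotype difference was tested for a change with transplantation in the design with the shared spread, which was planned, whereas leaving out genes listed at 0 and the tests of scaling, gene span, sex and splits were chosen after the results were seen.

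Genotype differences of 8 gene lists changed with transplantation by camera on the interaction, in which 0 members of any list passed over all genes. Cell cycle genes had a median interaction of -0.327 log2 (adjusted p = 3.5e-06; adjusted p = 0.406 with an estimated correlation). Their mean per endogenous library, centred per gene, was -0.054 and -0.03 in WT against 0.4 and -0.171 in KO, so KO replicate 1 alone lay above WT. Immediate early genes had 0.421 (adjusted p = 7.41e-05), megakaryocyte and platelet genes -0.224 (0.0106), TGF-beta, BMP, Notch and Wnt genes 0.324 (0.00125), HSC identity 0.224 (0.0106), HSC ageing and platelet bias 0.343 (0.0205), quiescence regulators 0.142 (0.0326) and heat shock genes 0.137 (0.0355). With an estimated correlation the adjusted p lay between 0.316 and 0.435. Without endogenous WT replicate 1 none of the 8 passed, with adjusted p of 0.0864 for the cell cycle, 0.716 for immediate early, 0.171 for megakaryocyte, 0.352 for TGF-beta, 0.384 for identity, ageing and quiescence, and 0.639 for heat shock genes. Without endogenous KO replicate 1 all but ageing (0.0481) were lost, with 0.303 for the cell cycle and 0.0855 for immediate early genes. Without endogenous KO replicate 2 identity (0.0641), quiescence (0.244) and ageing (0.215) were lost, and without endogenous WT replicate 2 megakaryocyte genes (0.17). Quiescence regulators were at 0.0507 with quantile normalization.

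By single gene 1365 interactions (11.6%) had an unadjusted p under 0.05, where chance gives a share of 0.05, and 4 interactions passed (limma). They were Ubc, listed at 0 in both endogenous KO libraries, Calr3, listed at 0 in both endogenous WT libraries and at 2.77 and 3.43 FPKM in endogenous KO (adjusted p = 0.0398), and 2 small RNAs at 0 in whole groups. Without genes listed at 0 in a whole group 0 passed.

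The pattern in primary libraries, lower cell cycle and megakaryocyte RNA and higher immediate early RNA in KO, was set against 3 technical explanations. Under median-of-ratios rescaling and quantile normalization all 3 lists kept their direction with an adjusted p of at most 2.96e-05 by camera. Median-of-ratios moves all genes of a library nearly alike, and camera sets a list against the other genes, so it could hardly change the result. Only quantile normalization argues against the authors' scaling as the cause. With the trend of gene span removed the adjusted p was at most 1.45e-06 by camera, which argues against that trend as the cause. Gene span includes introns, so a bias of transcript length was not tested. An unequal share of the sexes among donors or cells stays open, since Xist and the 4 Y-linked genes differed between the groups and 7.5% of X-linked genes were called against 8.2% of autosomal genes, which does not bound what sex does to autosomal genes, so sex and genotype cannot be told apart. Of the 10 splits of these 6 libraries 1, the real one, gave as many as 963 calls, with 2 calls as the highest other, and with the shared spread all 10 gave the 0 calls of the real one, with 0 as the highest other; 10 splits are too few for a share under 0.05. Xist and Y-linked RNA lay close together within each group, so its libraries may be parts of 1 pool. Genotype could then not be told apart from a difference between 2 pools. A lasting effect of the mutant stroma on HSCs is a hypothesis that these tests leave open beside litter or recipient differences, which were untested. Also untested were differences in DNA linked to the floxed Ebf1 allele, which HSCs of the KO donors carried themselves.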

How the results depend on the processing

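Fits of only the 2 groups compared were planned, while their own alternatives, their list tests, the removal of genes at 0 and the gene-span correction were chosen after the data were seen. Apart from left-out libraries, 110 values kept their direction and side of the threshold, 37 moved, 5 reversed and 1 became stronger; with a library left out, 167 kept, 59 moved and 12 reversed. The cause was not tested except where fewer genes or libraries entered. Transplantation calls stayed within 1.5 times under every alternative run.

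Endogenous calls (173) became 379 without a filter, 50 at a mean of at least 5 FPKM, 3 with library quality weights, 287 without a trend and 2 with 2 groups. Primary calls (0) became 4 without a filter, 3 with quantile normalization, 1493 with weights and 963 with 2 groups. Mean-effect calls (3) became 25 with a pseudocount of 0.1, 74 without a filter, 41 without a trend and 0 without genes at 0, and interaction calls (4) became 26, 93, 20 and 0. Lists called with an estimated correlation were 0 for the endogenous (of 4), 3 for the primary (of 16), 0 for the mean (of 5), 0 for the interaction (of 8) and 0 for the transplantation effect (of 6), and with fry 4 for the endogenous (the same 4), 2 for the primary, 4 for the mean, 1 for the interaction (T and NK cell markers, not among the 8) and 26 for the transplantation effect. With a pseudocount of 0.1 the correlation of genotype effects was -0.07 at p = 0.0333.

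The replicate numbers did not pair the primary RNA libraries, since same-numbered deviations correlated at -0.029, -0.16 and 0.012. In endogenous libraries they correlated at 0.28, from 2 pairs that mirror each other and are too few to decide. Oxidative phosphorylation means also lay by number (0.239 and 0.288 against 0.88 and 0.829), as did 4206 peak regions. So did endogenous Xist, at 8.71 and 12.97 FPKM in WT and KO replicate 1 against 27.45 and 32.33 in replicate 2. Uty, Kdm5d and Eif2s3y were higher in both replicate 1 libraries, while Ddx3y did not lie by number (22.88 and 14.95 against 21.56 and 7.67). An unequal share of the sexes between endogenous replicates was not tested as a source of these patterns. With the replicate block, endogenous calls were 3, primary calls of the 2-group fit 200 (90 higher, 110 lower) and mean-effect lists 8. For peaks the exact permutation within blocks gave p = 0.594 for number and 0.734 for length. Transplantation with the block was not run, as the block lies within status.

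At a -log10 q of at least 5 the covered-length difference between genotypes was 0.24 Mb, primary minus endogenous peaks 3006 and secondary minus endogenous 1944, all reversed. One-genotype regions were then 1403 in endogenous and 181 in secondary libraries, and with equal numbers of strongest peaks 885, 1598 in primary and 199 in secondary libraries. With equal numbers the persistence difference reversed, from -0.97 to 1.47 points in primary and from -0.81 to 0.11 in secondary libraries. Pooled lists at that q held 10571 WT-only and 6162 KO-only endogenous, 10930 primary KO-only and 10654 secondary KO-only peaks.

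With 1 library left out, where a lone library is assumed to vary like the other groups, calls ranged from 3 to 3824 (endogenous), 0 to 3 (primary), 3 to 2895 (mean), 3 to 2838 (interaction), 6228 to 8730 (transplantation) and 287 to 1104 (2 primary groups). Lists ranged from 2 to 8, 15 to 17, 3 to 8, 1 to 14 and 4 to 6 for the first 5. The correlation ranged from -0.099 to -0.02, the peak difference from -5576 to 418 (without endogenous WT 2), length from -1.58 to 0.09 Mb (without primary WT 1), and status differences from -9345 to -356, -10832 to -1842 and -3694 to 787, the last also 722 without primary WT 1. One-genotype regions ranged from 5139 to 35063, 7256 to 11052, 742 to 1095 and, over all 14, 0 to 3, since fewer lists must match. Persistence ranged from -8.28 to 1.62 in primary (0.38 without endogenous KO 1, 0.73 without primary WT 2) and -2.9 to 0.73 in secondary libraries. Similarity ranged from -0.016 to 0.02 (0.007 without endogenous WT 1, 0.002 without secondary WT 2, 0.017 without secondary WT 3). Promoter and motif analyses were not run. Unknown depth limits the numbers of peaks.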

Other observations

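All tests of explanations in this part were chosen after the results were seen, while the gene lists were fixed before.

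Further lists were tested in the fit of the 6 primary libraries. Heat shock and unfolded protein genes split, with 3 of 34 higher and 4 lower (5 and 8 adjusted over the list alone) and no shift of the list as a whole (camera adjusted p = 0.612). Ppp1r15a, which restarts translation after stress, rose by 0.57 and Hspa1a by 0.39 log2, and Sdf2l1 of the endoplasmic reticulum fell by 0.35. The 4 lower became 1 without WT replicate 1 or 3 and 2 without WT replicate 2 or KO replicate 3. Adhesion and niche genes also split (6 higher and 5 lower of 45, 10 and 6 adjusted over the list alone; camera adjusted p = 0.237), with Jam2 at 0.31, Cd9 at -0.32 and Itgb2 at -0.35 log2. They passed with quantile normalization (0.0345, 7 higher and 3 lower), and without any 1 library but KO replicate 2 the members called were 1 to 3 higher and 2 lower. Of 9 endothelial markers 3 rose and 0 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.0132; adjusted p = 0.135 with an estimated correlation), with Ramp2 at 11.9 and 18.7 FPKM, and the 3 became 1 without WT replicate 1 or 3 or KO replicate 1 or 3. Of 27 p53 targets 4 rose and 1 fell (5 and 4 adjusted over the list alone; camera adjusted p = 0.0085; adjusted p = 0.114 with an estimated correlation), with Plk2 at 0.34 and Gdf15 at 0.43 log2, and the 4 became 1 without any 1 WT library and 2 without KO replicate 1 or 3. Inflammation genes passed as a list (camera adjusted p = 0.0464; adjusted p = 0.167 with an estimated correlation) with 0 of 28 members called, and lost that call with median-of-ratios rescaling (0.0503), quantile normalization (0.0931), no filter (0.213) and without WT replicate 3 (0.134), KO replicate 1 (0.0612) or KO replicate 2 (0.127).

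The remaining lists did not pass there, with camera adjusted p of 0.0606 for the erythroid programme (0.0438 without a filter, 0.0486 with quantile normalization and 0.0402 with the trend of gene span removed), 0.0864 for mast cell and basophil, 0.16 for T and NK cell and 0.512 for monocyte markers, 0.188 for TGF-beta, BMP, Notch and Wnt genes, 0.271 for the lymphoid and 0.612 for the myeloid programme, 0.512 for ribosomal proteins, 0.612 for chromatin regulators, 0.698 for B and plasma cell markers, 0.71 for glycolysis and 0.814 for stromal markers. For the B and plasma cell and the stromal markers the median was below 0 (-0.00745 and -0.0248) while the test pointed up. Prg2 and Fcer1a of eosinophils and mast cells fell while Prss34, a basophil protease, rose by 0.71 log2.

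Thg1l, chosen for its place after its value was seen, lies on chromosome 11 (mm10, 45945305 to 45955503), within 2 Mb of Ebf1 (44618100 to 45008096). Of 13 tested genes in that window 2 were called in the primary libraries, Thg1l and Ublcp1 (0.31 log2, limma adjusted p = 0.0268), against 8.2% of all tested genes. Whether DNA linked to the floxed Ebf1 allele accounts for either was not tested.

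Lower immediate early and oxidative phosphorylation RNA in transplanted libraries was set against gene span and batch. With the trend of gene span removed, their medians were -1.717 (from -1.747) and -0.772 (from -1.075) log2, which argues against that trend as the whole cause of either. Of 100 splits of the 10 libraries 1, the real one, gave as many as 7066 calls, with 3 as the highest other. This is the smallest share that 100 splits can give. It bears on chance only if the libraries were independent, which no label states. Library or sequencing batch stays open and cannot be told apart from transplantation, since every primary library differed from every endogenous one (highest correlation 0.881, against 0.905 or more between replicates), Rps27 and Rps27rt changed places, and the notes name 2 versions of bcl2fastq. Loss of immediate early RNA in transplanted HSCs, for example from less activation during sorting, may contribute and was not tested.

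Higher erythroid RNA in endogenous KO libraries was set against single libraries. Erythroblast RNA in KO replicate 2 alone as the whole cause is argued against by the erythroblast markers without that library (camera adjusted p = 0.00992), though it may account for its globins, which were 5.25 log2 above WT there and 1.05 in KO replicate 1, while the other 22 erythroid genes were 0.05 and 0.62 above. That argument rests on the effect size in KO replicate 1 alone. There 14 of 15 erythroblast markers were above WT, with a median of 0.93 log2. The adjusted p cannot carry the argument, since a lone KO library is assumed in that fit to vary like the other groups. It shows no more than that KO replicate 1 was higher as well. Low values of WT replicate 1 stay open as a cause. Without it the call ended (adjusted p = 0.228) while the 15 markers went from a mean of 1.465 (SD 1.71, median 0.64) to 1.203 log2 (SD 1.25, median 0.99), and the call also ended without KO replicate 1 (0.111) or WT replicate 2 (0.185), with medians of 0.30 and 0.28, so with so few libraries no single one is singled out. An effect of mutant stroma on erythroid priming is a hypothesis that stays open and was not tested.

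For the mean genotype effect, 41 of 60 splits gave at least its 3 calls, so chance is not excluded, and the highest other split called 2640 genes, which points to a structure of the samples other than genotype, or to a spread shared between groups that vary unequally, which alone made 451 false calls in simulated libraries. That simulation gave more false calls than the 3 real calls, so its number does not carry over to these libraries. The structure and the shared spread were not tested apart.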
